A study of Xenopus laevis with 3 samples.

How the data were processed

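Whole tadpoles of Xenopus laevis at NF stage 42 were frozen, and total RNA was extracted with TRIzol from pools of 10 tadpoles per cross. Ribosomal RNA was depleted before library construction, per the labels' protocols. There were 3 libraries, with 1 per group (inbred albino, inbred pigmented J strain, and albino by J strain crosses), so no group has a replicate. Groups follow the sample titles. The strain letter codes given elsewhere in the labels contradict each other, since the albino library carries one code in its description and the opposite one in its genotype, and no result here depends on them.

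The submitters' processing notes name CASAVA 1.8.2, Trimmomatic, TopHat and SAMtools without a role or order. Aligner settings, the variant caller, its filters and the genome build are not given in the sources used here. The authors deposited 3 tables, all of the whole series. The first holds counts of variant sites per gene, as the authors deposited them: amino acid changing sites, split into benign, possibly damaging, probably damaging and without a prediction, and synonymous sites. The second holds 1 entry per protein position and change, with the PolyPhen-2 class and the predicted probability of damage, a fraction from 0 to 1 per the file headers, and the number of aligned residues behind it. Possibly damaging sites start at a probability of 0.447 and probably damaging sites at 0.909 in that table. The third pairs gene names with an L and an S copy. Read depth per site or per library was not analysed here, so no correction for depth or expression was made. Synonymous sites of the same gene were used as the internal control for this.

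The per-gene table has 11604 entries, of which 1 is a header line counted as a gene and was left out, leaving 11603. The class counts of all 11603 genes equalled the tallies of the per-site table. Each listed gene has at least 1 missense site, so genes with synonymous sites alone are outside every fraction. Names come from the pair table (8660 pairs, 6830 with a symbol), and 4452 listed copies had a symbol. The genes hps4 and tyr, planned for naming, carry no name there and were not analysed here. Chromosome coordinates were not used here. A comparison of the strains had been planned for the case that a column named a strain, and was not made.

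The missense fraction is missense sites over missense plus synonymous sites, pooled over genes. The damaging share is possibly plus probably damaging sites over sites with a prediction. Intervals (95%) resampled genes or pairs 10000 times, and shares of single genes have Wilson intervals, which cover counting error only. Exceptions are the intervals for the direction of base changes, which used fewer resamples of genes. The S share among pairs with a single copy listed has an exact binomial interval. L and S copies were compared by a two-sided permutation test that swapped copies within pairs. Genes inside and outside the pair table were compared by shuffling that label, and gene lists by drawing random lists of the same size, each with 100000 resamples. The smallest p these tests can give is 2e-05. Single genes with at least 5 sites (5 predicted sites for the damaging share) were compared with all other genes by Fisher's exact test, two-sided. Adjustment was by Benjamini-Hochberg with a threshold of 0.05, over genes or over lists.

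The tests, the alternatives and 26 gene lists were fixed before the data were examined, with exceptions named here. Lists with fewer than 5 listed copies were not tested, which left 22: antigen presentation had 1 listed copy, cytosolic ribosomal proteins 0, histones 2, and haemoglobin and erythroid genes 3. The plan set each list against all other genes. Because a gene without a symbol cannot enter a list, the main comparison departed from the plan and used the listed genes with a symbol. The lists that passed against all listed genes are named beside it.

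Named genes followed a rule set beforehand, among genes with a symbol. It took the 12 with the most damaging sites, the 8 with the smallest p above and the 8 below the overall missense fraction, and up to 6 with the smallest p each way for the damaging share. It also took the 6 pairs that differ most in missense sites and, for pigmentation and each list that passed, up to 4 members with the most damaging sites, then the most missense sites. Ties for the most damaging sites went to the larger ratio of damaging to synonymous sites, with 0 synonymous sites set to 0.5. Within a gene, the example site is the one with the highest predicted probability. Other names are said to have been chosen after their values were seen.

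Alternatives were probably damaging sites only, a predicted probability of at least 0.9, at least 10 aligned residues, at least 10 sites per gene, no minimum, leaving out the 1% of genes with the most sites (116 genes with more than 30 sites), means over genes with at least 5 sites in the denominator, matched random lists, and all listed L and S copies compared unpaired. Alternatives added after seeing the data were genes with a prediction at every missense site (9413), pairs with a symbol, sites without a prediction counted as not damaging, labels shuffled within bins of total sites, lists drawn by gene name, lists against all listed genes, and lists without the member with the most sites. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

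The tests were tested on simulated data made from the real genes. For the per-gene missense test over 4910 genes, 31% of genes with 4-fold odds and 7% of genes with 2-fold odds were called, and 0 of 4710 unchanged genes. The changed genes were drawn only from genes with many sites, so the share called among genes with few sites was not measured. For lists over 4452 copies, 4% passed an unadjusted p of 0.05 with no effect and 86.8% with the missense odds multiplied by 0.5. These lists held 31 copies each, and their copies could fall to 0 missense sites, which listed genes cannot. For the swap test over 1329 pairs, 6.25% passed with no effect and 100% with S odds multiplied by 1.3. For lists and for the swap test, the data with no effect were drawn as the test itself draws its resamples. A share near the threshold was therefore built in, and it checks the code rather than how the tests behave on the real data.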

Results

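Coding sequence variation was examined in Xenopus laevis, the African clawed frog, from RNA sequencing of whole tadpoles at Nieuwkoop-Faber (NF) stage 42. The species is allotetraploid, and many of its genes exist as homeologs, a pair of copies that lie on the long (L) and the short (S) subgenome. There were 3 libraries: 1 from an inbred albino cross, 1 from an inbred cross of the pigmented J strain, and 1 from crosses between those strains. RNA came from 10 pooled tadpoles per cross, and depth was stated as 30000000 to 47000000 paired-end reads of 100 bases for each library. The values analysed here describe the series as a whole. No column names a library or a strain, so the crosses were not compared with one another and no spread between replicate libraries could be measured. Intervals (95%) were taken over genes, homeolog pairs or sites, and tests treat these as units. Copies are written with their subgenome, as in nes.L and nes.S.

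The first question was how many coding variants change the protein and how many of those were predicted to harm it. Genes with an amino acid change numbered 11603, with 29008 missense and 38655 synonymous sites. Among genes with a symbol, the highest numbers of damaging sites were in ahnak-like.S (Xelaev18024207m), a giant scaffold protein, with 16, and nes.L (Xelaev18040537m), which encodes nestin, an intermediate filament of neural progenitors, with 12. The copies mia3-like.1.S, related to a factor for collagen export, and ank3.L, an ankyrin that anchors membrane proteins to the spectrin skeleton, held 7 each. Both copies of palb2, which encodes a partner of BRCA2 in DNA repair, held 6, as did tbc1d10b.S and tsc22d2-like.S. The ETS factor elk4.S, the stress-response factor ddit3.S, the elastin gene eln2.S and the receptor phosphatase ptprz1.S held 5 each; other copies also held 5, and these 4 have the most damaging sites relative to synonymous ones.

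Of the 24110 missense sites with a prediction, 80.1% were benign, 13% possibly damaging and 6.96% probably damaging. Damaging sites of both classes made up 19.9% (19.4 to 20.5 when genes were resampled), and 4898 missense sites (16.9%) had no prediction. Missense sites were 42.9% of all coding sites (42.3 to 43.4). This fraction is raised by the way the genes were listed, because every gene in the table has at least 1 missense site and genes with synonymous sites alone do not enter. The median gene held 1 missense and 2 synonymous sites, 5878 genes (50.7%) held a single missense site, and 3470 genes (29.9%) held at least 1 damaging site.

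The next comparison asked whether single genes held more or fewer amino acid changes than the rest. Among genes with a symbol and a high missense fraction, those with the smallest p were nes.S (Xelaev18042775m), with 15 missense sites and 1 synonymous site (93.8%, Fisher's exact adjusted p = 0.0107), and fgfbp3.S, a fibroblast growth factor binding protein, with 16 and 3 (84.2%, adjusted p = 0.0354). The chromatin remodelling factor bptf.S followed with 14 and 2 (87.5%, Fisher's exact adjusted p = 0.0418), and the nuclear receptor corepressor lcor-like.S with 9 and 0 (adjusted p = 0.0422). Among genes with a symbol and a low fraction, those with the smallest p included the axonemal dynein dnah3.S (Xelaev18047641m), with 1 missense and 26 synonymous sites (3.70%, Fisher's exact adjusted p = 0.00476), the cytoplasmic dynein dync1h1.S, with 7 and 42 (14.3%, adjusted p = 0.0107), and the coatomer subunit copa.L, with 1 and 23 (4.17%, adjusted p = 0.0107). The genes trrap-like.S, a scaffold of histone acetyltransferase complexes, supt6h.S, a transcription elongation factor, and abca3-like.S, a lipid transporter, each held 1 missense site, against 23, 22 and 21 synonymous sites (Fisher's exact adjusted p = 0.0107, 0.0152 and 0.0202). The trafficking genes dopey2.L and arfgef2-like.L held 2 missense sites each, against 26 and 24 synonymous sites (Fisher's exact adjusted p = 0.0152 and 0.0283).

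Over 5005 genes with at least 5 sites, 66 passed Fisher's exact test (two-sided) after Benjamini-Hochberg adjustment, 31 with a higher and 35 with a lower missense fraction than all other genes. Of these, 4 of the higher and 16 of the lower genes had a symbol, and 543 genes had an unadjusted p under 0.05. Outside the pair table lay 21 of the higher and 16 of the lower genes, so the named genes do not represent the higher ones. The surface phosphatase ptprc.L (14 and 3, Fisher's exact adjusted p = 0.0755), the death receptor tnfrsf10b.L (8 and 0, adjusted p = 0.0755), akap13-like.S (26 and 12, adjusted p = 0.0999) and c6orf136.S (7 and 0, adjusted p = 0.132) did not pass. The number of genes passing moved with the setting: it was 28 with no minimum of sites, 14 without the 1% of genes with the most sites, and 94 with at least 10 sites, of which 67 were higher. The last setting also took its reference from genes with at least 10 sites, whose missense fraction was lower than that of all genes. The balance of higher and lower genes thus depends on the reference. Leaving out the genes with the most sites removed 20 of the 66 from the test. Under the first 2 settings, fgfbp3.S, bptf.S, lcor-like.S and arfgef2-like.L no longer passed, while ptprc.L and akap13-like.S passed with at least 10 sites (Fisher's exact adjusted p = 0.0112 and 0.00879).

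**Figure D1:**
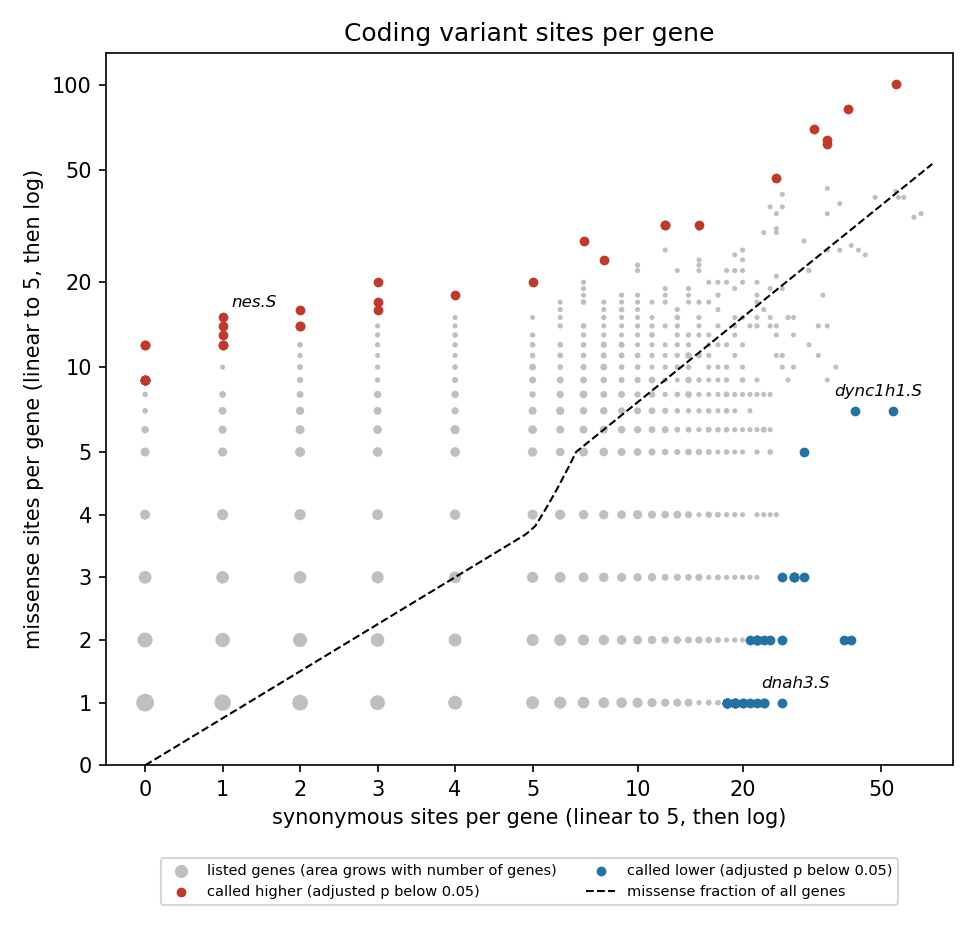
Missense against synonymous sites for the 11603 listed genes, with both axes linear to 5 and logarithmic from there; grey points grow with the number of genes at a position, and the dashed line is the missense fraction of all genes (42.9%). The 31 genes called higher (red) lie above the line and the 35 called lower (blue) lie under it.

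No gene passed the same test for its damaging share among 1112 genes with at least 5 predicted sites, by Fisher's exact test with Benjamini-Hochberg adjustment, and 35 had an unadjusted p under 0.05. Among genes with a symbol, the lowest p was that of ahnak-like.S, with 16 of 35 predicted sites damaging (45.7%, Wilson interval 30.5 to 61.8, Fisher's exact adjusted p = 0.249). The copies elk4.S, eln2.S and ptprz1.S had 5 of 6 each (83.3%, Fisher's exact adjusted p = 0.249), mia3-like.1.S had 7 of 11 (adjusted p = 0.266) and tsc22d2-like.S had 6 of 10 (adjusted p = 0.566). The site with the highest predicted probability within each gene was, for example, P871A in ahnak-like.S (0.999), L305P in elk4.S (0.999) and K1696I in mia3-like.1.S (0.996). The reference residue comes first and positions are counted in the authors' protein models. These sites rested on 187, 62 and 71 aligned residues, and that of ank3.L on 33. Far fewer lay behind the top sites of ptprz1.S (8), eln2.S (5), nes.L and ddit3.S (3 each) and palb2.S (2). The top sites of palb2.L, tbc1d10b.S and tsc22d2-like.S had 1 each. The alternative with at least 10 aligned residues was not run for single genes. At the other end, the apolipoprotein gene apob.L had 0 of 18 predicted sites damaging (Wilson interval 0 to 17.6%), the histone demethylase kdm7a.S had 0 of 14 and ccdc88a-like.L 0 of 9. The receptor gpr116.S had 1 of 16, and nbeal2.S and ptprc.L had 1 of 14 each (Fisher's exact adjusted p = 1 for these 6 genes). When only probably damaging sites were counted, ahnak-like.S passed (Fisher's exact adjusted p = 0.0176), as it did at a predicted probability of at least 0.9 (adjusted p = 0.0296).

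The gene lists asked which kinds of genes held more or fewer amino acid changes. Translation factors and aminoacyl-tRNA synthetases, which build proteins and charge tRNAs, had the lowest missense fraction: 64 missense and 194 synonymous sites in 31 listed copies, or 24.8% (20.8 to 29.4) against 38.7% in the other genes with a symbol. The members with the most damaging sites, which need not have a low fraction, were the valyl-tRNA synthetase vars.L with 8 and 23 sites, the elongation factor kinase eef2k.S with 3 and 3, the aspartyl-tRNA synthetase dars.S with 2 and 2, and the glutaminyl-tRNA synthetase qars.L with 2 and 5. Among other copies, named after their values were seen, iars.L held 6 and 18 and kars.L 6 and 16. The copy gars.L, named in the same way, had a low fraction, with 1 and 13. Of the 18 tested copies of the list, 0 passed over all genes tested. When adjusted over the list alone, 1 passed: vars.S, with 1 missense and 15 synonymous sites, named after its value was seen. The list passed a two-sided permutation test over 22 lists (adjusted p = 0.0238), and its call was lost against random lists matched on total sites (adjusted p = 0.0572), as a mean over genes (0.0664) and with at least 10 sites per gene (0.489).

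The ion channel and synapse list, which holds channels, neurotransmitter receptors and synaptic genes such as synaptotagmins, had 30.6% missense (25.1 to 37.2) in 61 copies, which did not pass (permutation adjusted p = 0.137) but passed against matched lists (adjusted p = 0.0211). The taste-cell channel trpm5-like.S, with 1 missense and 18 synonymous sites, was the 1 gene of this list that passed over all genes tested (Fisher's exact adjusted p = 0.0481). It also passed when adjusted over the list alone and was named after its value was seen. Its adjusted p was close to the threshold, and it was not among the 28 genes that passed with no minimum of sites. Respiratory chain and ATP synthase subunits had 55.6% missense in 17 copies (44.3 to 72.2, permutation adjusted p = 0.142, or 0.744 against matched lists) and zinc finger proteins 45.1% in 84 copies (40.6 to 50.0, adjusted p = 0.184), with unadjusted p = 0.0194 and 0.0334. Among 16 cilium copies 38.5% of sites were missense (permutation adjusted p = 0.968), with dnah3.S passing in both ways of adjusting. Adjusted over the list alone, tnfrsf10b.L of the innate immunity genes also passed, with a high fraction (8 missense and 0 synonymous sites). Of the signalling genes, notch1.L (3 and 22), jag1.S (2 and 16) and lrp6.S (1 and 13) passed in this way with low fractions. So did myh9.S (2 and 17), which the muscle list holds although it encodes a non-muscle myosin. Apart from tnfrsf10b.L, these genes were named after their values were seen. None of these 5 passed over all genes tested. With all listed genes as the comparison, in place of those with a symbol, 3 lists passed: translation, ion channel and synapse, and extracellular matrix. The extracellular matrix list had 31.3% missense in 44 copies (26.7 to 37.1). Against genes with a symbol it did not pass (permutation adjusted p = 0.236).

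Pigmentation genes, of interest because the crosses involve albino animals, did not stand apart. Their 14 listed copies held 33 missense and 44 synonymous sites, or 42.9% missense (34.1 to 53.3, permutation adjusted p = 0.734). Damaging sites were 9 of 32 predicted (28.1%, 15.8 to 40.6, permutation adjusted p = 0.643) and lay in 6 copies. The copper transporter atp7b.S held 11 missense sites, 3 of them damaging, with C168F at a probability of 0.997. The Rab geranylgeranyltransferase subunit rabggta.S held 4, of which 2 were damaging, and the MITF-family factor tfec.S held 4, of which 1, P197S, was damaging (0.999). In oca2.L, a melanosomal transporter whose loss causes albinism in other vertebrates, 1 of 3 missense sites was damaging (S99I, 0.814). The single missense sites of oca2.S and vps33a.L were also damaging; these copies were named after their values were seen. None of the 6 copies tested passed, over all genes tested or when adjusted over the list alone, and no site can be assigned to the albino or the J strain here.

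For the damaging share, 0 of 22 lists passed the permutation test and 2 had an unadjusted p under 0.05. The ion channel and synapse list had 11.2% of predicted sites damaging (9 of 80, 4.94 to 18.6, permutation p = 0.00654, adjusted p = 0.144), and innate immunity genes 11.4% (9 of 79, 5.26 to 18.5, p = 0.0493, adjusted p = 0.455). Extracellular matrix genes had 29.1% (adjusted p = 0.455) and DNA repair and replication genes 27% (adjusted p = 0.643), by the same permutation test.

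**Figure D2:**
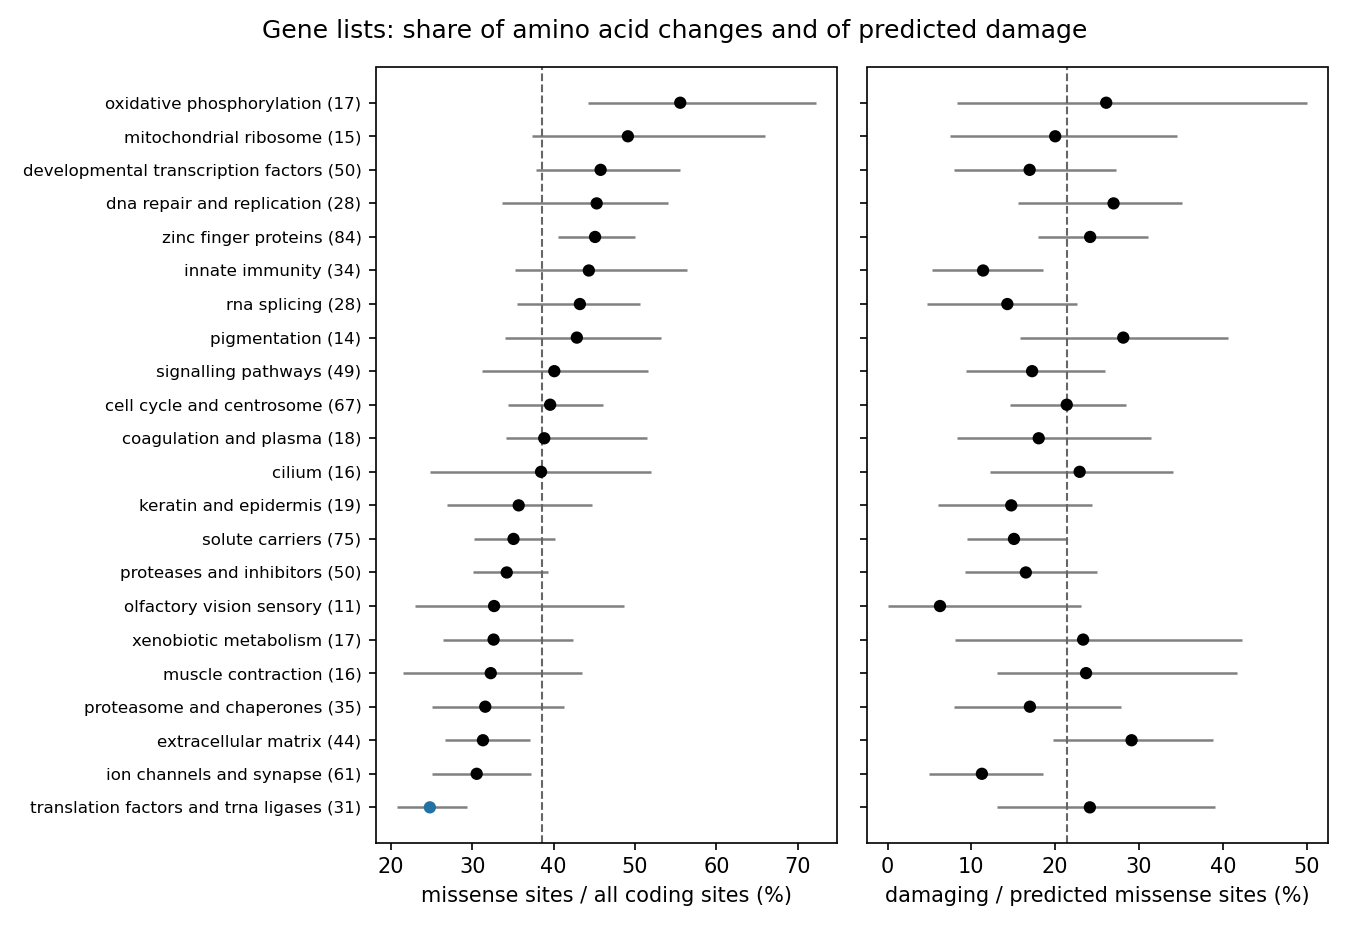
Missense sites as a percentage of coding sites (left) and damaging sites as a percentage of predicted missense sites (right) for the 22 tested lists, with the number of listed copies in brackets; lines are 95% intervals from resampling genes and dashed lines are the values of all genes with a symbol. Translation factors and tRNA ligases (blue, 24.8%) are the list that passed.

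The subgenomes were compared within homeolog pairs. S copies held more missense sites than L copies, and the named pairs with the largest differences mostly leaned the same way. The cytolinker dst held 10 missense sites in L and 42 in S, ahnak-like 5 and 35, the centrosomal anchoring protein akap9 11 and 37, the histone methyltransferase kmt2c 6 and 27, and akap13-like 7 and 26. Nestin was the exception among these 6 pairs, with 41 in nes.L and 15 in nes.S. Synonymous sites leaned the same way in each of these pairs: they numbered 14 in L and 55 in S for dst, 4 and 25 for ahnak-like, 14 and 26 for akap9, 11 and 41 for kmt2c, 6 and 12 for akap13-like, and 26 and 1 for nes. The missense fractions in L and S were 41.7% and 43.3% for dst, 35.3% and 39.7% for kmt2c, and 55.6% and 58.3% for ahnak-like. They lay farther apart for akap9 (44.0% and 58.7%), akap13-like (53.8% and 68.4%) and nes (61.2% and 93.8%). Over all 8660 pairs, counting an unlisted copy as 0, the mean was 0.719 missense sites per L copy and 0.862 per S copy, a difference of -0.143 (-0.194 to -0.0943). The two-sided permutation test that swapped copies within pairs gave p = 2e-05, the smallest it can give.

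In the 1329 pairs with both copies listed, S copies held more missense sites in 530 pairs, L copies in 410, and the counts were equal in 389. Missense sites averaged 2.75 in L and 3.21 in S (permutation p = 0.00012; p = 0.342 with at least 10 sites per gene), and synonymous sites 4.29 and 4.56, a difference of -0.270 (-0.575 to 0.0301, permutation p = 0.0788). The missense fraction was 39.1% in L and 41.3% in S, a difference of -2.21 percentage points (-3.95 to -0.432, permutation p = 0.0126). That call was lost with at least 10 sites per gene (-1.52, permutation p = 0.310) and when all listed L and S copies, not only those of these pairs, were compared unpaired (-1.27, p = 0.100). The damaging share, 21.5% in L and 21.9% in S, did not differ detectably (-0.399 points, -2.50 to 1.70, permutation p = 0.710).

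Copies in the pair table were compared with genes outside it. The 5667 genes of the pair table had a lower missense fraction (40.2%) than the 5936 genes outside it (45.6%), a difference of -5.39 points (-6.50 to -4.29, two-sided permutation p = 2e-05, the smallest possible). Their damaging share was higher, 21.0% against 18.9% (2.13 points, 1.04 to 3.20, permutation p = 1e-04). Sites without a prediction made up 13.3% of missense sites in the pair table and 20.1% outside it. Genes outside the table carry no symbol and are not shown to be single copies.

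**Figure D3:**
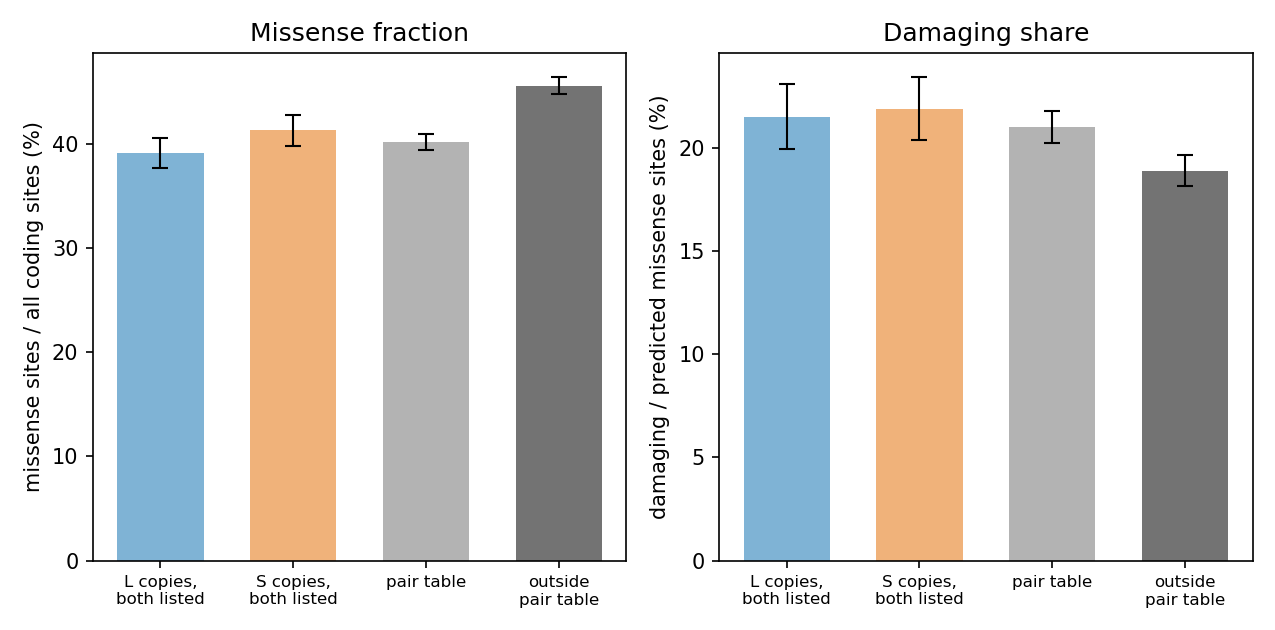
Missense sites as a percentage of coding sites (left) and damaging sites as a percentage of predicted missense sites (right) for L and S copies of the 1329 pairs with both listed, for all copies in the pair table and for genes outside it; bars are pooled values and error bars 95% intervals from resampling genes. The missense fraction is 39.1% in L, 41.3% in S, 40.2% in the pair table and 45.6% outside it.

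The last comparison asked whether predicted damaging sites and missense fractions went together in the homeologs of a gene. Damaging sites were found in both copies of palb2 (6 in L and 6 in S), kmt2c (4 and 5), the phosphodiesterase-binding protein gene pde4dip (5 and 4) and nes (12 and 3); these pairs were chosen after their values were seen. Predicted damaging sites lay in both copies in 210 pairs, in L alone in 247, in S alone in 298 and in neither in 574 (odds ratio 1.64, Fisher's exact p = 3.14e-05). No column names a library, so the sites of L and S may come from different crosses or animals. When S copies were shuffled within bins of total sites, 187 pairs were obtained on average (permutation p = 0.00362). These bins count missense and synonymous sites together, whereas a damaging site can lie only among predicted missense sites. Because the missense fractions of homeologs were themselves correlated, the shuffle cannot tell whether damaging sites went together beyond the number of missense sites. With at least 10 sites per gene the call was lost (odds ratio 1.48, Fisher's exact p = 0.298, within bins p = 0.536). The alternative with at least 10 aligned residues was not run on these pairs. Across 480 pairs with at least 5 sites in each copy, the missense fractions of L and S were correlated (Spearman's rho 0.316, Pearson's r 0.317, permutation p = 2e-05 for each, the smallest possible). This correlation is across genes, which are not independent replicates, and r was 0.303 without the 2 pairs farthest from the median in L.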

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

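The tests of mirrored changes, of base direction by kind of change, of arginine exchanges and of the missense fraction as a check on site numbers were chosen only after the results were seen; the test without the genes with the most sites and the test at well-aligned sites were not.

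At 388 of 28616 protein positions (1.36%, Wilson interval 1.23 to 1.5), in 354 genes, more than 1 non-reference residue was listed. This feature lies outside the reported comparisons, and no level from control samples was at hand to set it against. In homeolog pairs, 10 identical changes lay within 5 residues of each other in both copies, against a mean of 1.04 and an upper end of the 95% range of 3 in 1000 shuffled pairings (permutation p = 0.002, the smallest these shuffles can give). True pairs also held more pairs of sites within that distance, 240 against a shuffled mean of 100.1, and share homologous residues, so part of the excess follows from the choice of comparison.

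S copies held more missense sites than L copies. Reads exchanged in both directions between homeologs would leave mirrored changes, and 2 were found, against a shuffled mean of 1.09 and an upper end of the 95% range of 3. Such an exchange would add sites to both copies, so this count does not by itself bear on the excess in S. More sites of every kind in S copies would leave the missense fraction equal, and it differed by -2.21 points, although that call was lost with at least 10 sites per gene and among all listed copies compared unpaired. Without the 1% of genes with the most sites the difference in missense sites per copy was -0.111, so those genes are not the whole cause. Reads moving in one direction, coverage as a part of the cause, and weaker selection on S copies remain open as possible explanations, and no biological explanation was tested.

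Non-reference residues leaned towards changes from C or G to T or A: of changes that allow only one direction, 9898 went that way and 8242 the reverse (54.6%, 53.9 to 55.3 over genes). Oxidised guanine acts on transversions and cytosine damage on transitions, but transitions held 54.5% (53.7 to 55.4) and transversions 54.7% (53.4 to 56.1), which argues against either alone as the whole cause. The lean was not confined to sites with a poor protein alignment behind the prediction, since it was 55.4% at sites with at least 10 aligned residues. That value cannot test how the reads were aligned. Arginine exchanges with C, H or Q, where CpG sites can lie, leaned more (57.4%) than other transitions (54.2%, Fisher's exact p = 0.0222). The lean differed among them: arginine to C was 172 against 95, to H 291 against 206, and to Q 328 against 286. CpG transitions may thus add to the lean. CpG sites can also lie among the other transitions, so how much of the lean they account for was not measured. Both kinds of damage together, the alignment of reads, the caller and mutation in the strains remain open, and no biological explanation was tested.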

How the results depend on the processing

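Values recomputed under genes fully predicted, pairs with a symbol, unpredicted sites as not damaging, all listed genes as comparison, binned labels, lists by name and lists without their largest member were chosen only after seeing the data. Of 593 recomputed values, 536 were counted as unchanged, 26 moved, 17 were weaker, 8 stronger and 6 reversed. Unchanged means the same direction and side of the threshold, or a value within its margin. For a list or gene that passed in neither setting, a change of direction was also counted as unchanged. The excess of missense sites in S copies over all pairs, the correlation of homeologs (rho 0.240 to 0.534) and both differences between genes inside and outside the pair table kept direction and call in every alternative run on them. The damaging share of 19.9% became 6.96% for probably damaging sites only and 7.36% at a probability of at least 0.9, by construction, 19.1% with at least 10 aligned residues, 19.4% in fully predicted genes and 16.6% with unpredicted sites counted. The missense fraction became 37.6% with at least 10 sites per gene, 37.8% as a mean over genes with at least 5 sites and 40.3% in fully predicted genes. The L minus S missense fraction was -1.52 points with at least 10 sites and -1.27 for all listed copies, unpaired. The uncalled L minus S damaging share turned positive in 6 alternatives (0.163 for probably damaging, 0.290 at 0.9, 0.187 aligned, 0.895 with at least 10 sites, 0.413 as a mean, 0.0164 with a symbol), with p from 0.682 to 0.989. The odds ratio for both homeologs was 1.48 with at least 10 sites, where fewer pairs remained. Lists passing for missense fraction numbered 0 with at least 10 sites, 0 as a mean over genes, 3 against all listed genes and 2 in fully predicted genes. Genes passing for missense fraction numbered 28 with no minimum, 14 without the 1% of genes with the most sites and 30 in fully predicted genes, of which 28, 14 and 29 were among the 66 (20 of these left the test in the second); with at least 10 sites there were 94 (67 higher), of which 53 were. For the damaging share 1 gene passed for probably damaging sites and 1 at 0.9. Elsewhere the cause was not tested. No paired analysis was possible because the groups share replicate number 1 alone and no column names a library. The strain comparison was not run.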

Other observations

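The tests of which copies were listed with a missense site, of their S share and of exchanges between residues were chosen only after the results were seen.

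Gene groups differed in how many of their copies had a missense site at all. Of 13660 copies with a symbol, 4452 (32.6%) were listed, and 9 of 26 lists differed from the other genes by a two-sided permutation test after Benjamini-Hochberg adjustment, 3 with more and 6 with fewer. Coagulation and plasma proteins, secreted by the liver, had 18 of 30 copies listed (60.0%, permutation adjusted p = 0.0223), DNA repair and replication genes 28 of 52 (53.8%, adjusted p = 0.021) and zinc finger proteins 84 of 186 (45.2%, adjusted p = 0.00607). Developmental transcription factors, such as Hox, Sox and Pax genes, had 50 of 364 (13.7%, permutation adjusted p = 0.00026), and signalling genes of the Wnt, BMP, FGF, Notch and Hedgehog pathways 49 of 242 (20.2%, adjusted p = 0.00156). Proteasome and chaperone genes had 35 of 176 (19.9%, permutation adjusted p = 0.00481), ion channel and synapse genes 61 of 268 (22.8%, adjusted p = 0.0052) and respiratory chain and ATP synthase subunits 17 of 96 (17.7%, adjusted p = 0.0158). No correction was made for expression or coding length.

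Of 54 cytosolic ribosomal protein copies, 0 were listed (permutation adjusted p = 0.00026), which allows a share of up to 5.56% (3 copies of 54). Of 44 mitochondrial ribosomal protein copies, 15 were listed (34.1%, Fisher's exact p = 1.26e-06 between the groups). Coding lengths of the groups were not compared, so this does not decide whether short coding sequences are the cause. Whether reads that map to several copies or pseudogenes were not used for calls cannot be told apart from strong conservation: 0 synonymous sites are listed for these copies, but only genes with a missense site are listed. Strong conservation may contribute and was not tested.

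Of pairs with 1 copy listed, 1628 had the S copy and 1381 the L copy (54.1% S, 52.3 to 55.9, exact binomial p = 7.22e-06). Among 75 exchanges between residues, 16 were uneven after adjustment, 14 of them from C or G to T or A and 0 the opposite way. For example, arginine to cysteine occurred at 172 sites and the reverse at 95, and proline to leucine at 329 and 229. By reference residue, the damaging share was highest for proline (37.1%) and glycine (36.0%) and lowest for methionine (3.30%). By new residue it was highest for tryptophan (51.3%) and cysteine (50.3%). In the 31 genes with a high missense fraction, 298 of 844 missense sites (35.3%) had no prediction, against 15.2% in the other tested genes (permutation p = 0.0647). Without the 3 of these genes that held the most such sites, it was 94 of 591 (15.9%). Those 3 were picked by that number and none were left out of the other genes, so a lower share was bound to follow. In 6 of the 31 genes, most missense sites had no prediction.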
